A study of Withania somnifera with 6 samples.

How the data were processed

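Leaf RNA of *Withania somnifera* (ashwagandha, a medicinal plant of the nightshade family) was measured in 6 libraries, 3 from control plants and 3 from plants given sodium chloride. Per the labels' protocols, all plants grew for 70 days at 21 °C on Hoagland's solution, a complete mineral nutrient solution. The salt plants then received daily doses of 200 ml of that solution with 100 mM NaCl for 1 week. Per the series' design text, 3 leaves were collected per plant. Total RNA was extracted with a column kit, and stranded total-RNA libraries were made after ribosomal RNA depletion, per the labels' protocols. The submitters' processing notes name FastQC, Trimmomatic 0.39 and RSEM. The aligner, the assembler and its settings, the strand setting and the RSEM version are not given in the sources used here.

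The authors deposited 1 RSEM table per library, with 1 row per isoform. All 6 tables list the same 241790 isoforms, grouped under 165614 gene identifiers of the form that the Trinity assembler writes. In such an assembly a "gene" is a cluster of assembled transcripts, so it can be a part of a locus, and near-identical copies can share reads. The deposited expected counts are RSEM's estimates of the reads or fragments from each isoform. They need not be whole and are not scaled for depth, per the file headers and the values. The deposited TPM values are the same estimates divided by effective length and scaled by the authors to the same sum in each library. The deposited FPKM values, scaled by length and total, entered no test. The deposited isoform percent is the share of a gene's abundance that RSEM gave to each isoform, and it also entered no test. The tables pair no identifier with a gene name, a product or a position, and no sequence or annotation was used here. The 21 gene lists fixed with the tests and the alternatives before the data were examined (ion transport, osmolytes, abscisic acid, photosynthesis, withanolide synthesis and others) therefore could not be tested.

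Expected counts were summed per gene and rounded to whole numbers. Genes were filtered with filterByExpr at its minimum count of 10, scaled with TMM factors and tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) in its robust quasi-likelihood test, salt minus control, with Benjamini-Hochberg adjustment over the 23666 genes tested. These genes held 98.4% of all counts. A gene was called at an adjusted p under 0.05, two-sided. Isoforms were tested in the same way, and isoform usage with diffSpliceDGE and Simes p-values per gene. Standard errors of log2 fold changes were taken as the log2 fold change over the square root of the test's F. CPM values use TMM-scaled totals. Genes present in 1 group only were those with at least 10 counts in each library of that group and 0 in each library of the other. Library-level values were compared with exact permutation tests, two-sided, for which 3 libraries against 3 allow no p under 0.1. The rule for named genes, fixed with the tests, takes the 2 that rose and the 2 that fell most among called genes whose salt and control libraries did not overlap and whose mean log2 CPM was at least 1.

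Each library was also written as a weighted sum of the other 2 of its group, with non-negative weights fitted on a random part of the genes with at least 200 counts in those 2 libraries and tested on the rest. The third library of each group lay between the first 2, as described with the results. The gene, isoform, usage and presence tests and the library-level tests were therefore also run without both libraries 3, an alternative added after this was seen. Other alternatives were DESeq2 1.42.0, limma-voom, other scalings and filters, TPM in place of counts with a pseudocount of 1, each library left out, and the replicate number as a block. Library-total scaling without the 20 most abundant genes and edgeR's newer quasi-likelihood method (legacy = FALSE) were also added after the data were seen. No label says that plants of equal number were paired, and the numbers were not taken as pairs.

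The functions were tested on simulated data. At gene level, with 23666 genes and separate plants, the test recovered 16.4% of genes changed 2-fold, 77.6% of those changed 4-fold and 89.4% of those changed 16-fold, with 15 false calls. The spread simulated there was that estimated from all 6 libraries, so recovery with separate plants can be lower. At isoform level, with 48437 isoforms, it recovered 0% at 2-fold, 4.48% at 4-fold and 34.8% at 16-fold, with 1 false call. For isoform usage, with 9823 genes, 25.5% of 4-fold and 72.5% of 16-fold switches were recovered, with 19 and 23 false calls. With no gene changed, 20 simulations over 25248 genes gave a median of 1.5 calls where library 3 of each group was a separate plant. They gave a median of 328.5 calls (range 203 to 465) where library 3 of each group was an even mix of the first 2. Those simulations used the spread of the 4 libraries numbered 1 and 2, drawn independently for each separate plant.

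Library totals ran from 12465622 to 18671973 expected counts. A count of 0 allows up to 3 counts, which is 0.150 to 0.247 CPM on the TMM-scaled totals, depending on the library and covers counting error only. The series' design text names separate plants within each group.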

Results

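RNA sequencing of ribosomal-RNA-depleted leaf RNA gave 6 libraries of *Withania somnifera*, 3 labelled as control plants and 3 as plants watered with 100 mM NaCl for 1 week. The design asks how the leaf transcriptome differs after a week of high salt. Expected counts per library totalled 18671973, 15571561 and 12826546 in control libraries 1, 2 and 3, and 12465622, 15839160 and 14523435 in salt libraries 1, 2 and 3. The assembly to which reads were assigned held 165614 genes, of which 84.5% had a single isoform, and the median length of the longest isoform was 353 nt. The identifiers carry no gene names, so genes are described here by abundance, length and isoform number, and no pathway could be assessed.

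The libraries differed along 2 main directions. The first principal component held 40.1% of the variance and was lower in library 1 than in library 2 of each group. The second held 32.9% and lay between 5.69 and 61.2 in the control libraries and between -62.9 and -7.07 in the salt libraries. In each group the third library lay between the first 2. Of 4529 genes not used for fitting, 82.9% had a share of counts in control library 3 that lay between those in libraries 1 and 2, and in salt library 3 the value was 66.2% of 3379 genes. A weighted sum of libraries 1 and 2 gave the counts of library 3, with weights of 0.36 and 0.39 in control and 0.48 and 0.53 in salt. Among genes with at least 1000 counts in the 2 fitted libraries together, library 3 departed from that sum by 2.89% in control and 2.50% in salt beyond counting error. This is a median-based coefficient of variation, which a few outlying genes do not move. The abundant control gene TRINITY_DN16876_c1_g1, for example, had 60026 counts against 48387 in the sum. The same median-based value was 29.2% and 37.6% for control libraries 1 and 2, and 17.5% and 13.8% for salt libraries 1 and 2. Their fits gave a weight of 0 to the other of libraries 1 and 2, so these values measure distance from library 3. Departures beyond 2-fold occurred in 2 genes of control library 3 and 1 gene of salt library 3. In the typical gene the libraries numbered 3 thus held little spread of their own, so standard deviations and p-values over 3 libraries understate the spread between plants. The main counts and library-level values are therefore given also without both libraries 3.

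**Figure D1:**
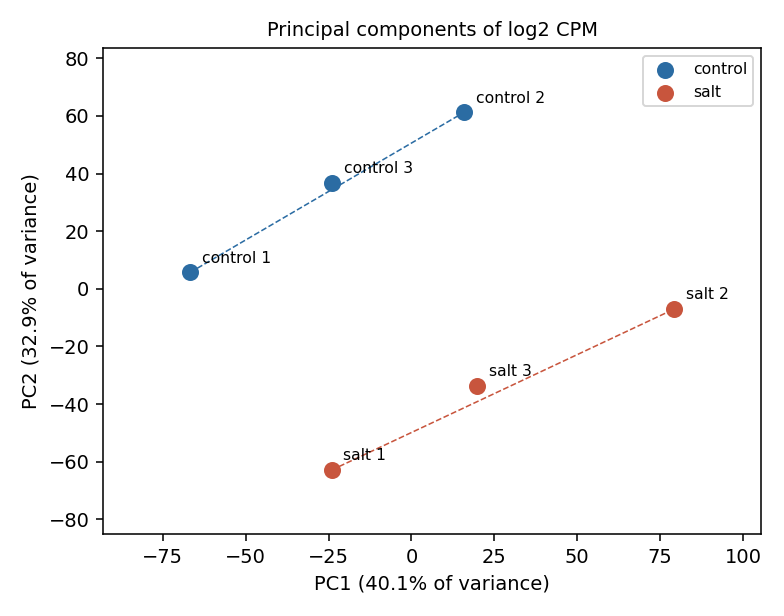
Principal components of log2 CPM over the 23666 tested genes, with PC1 (40.1% of the variance) on the x axis and PC2 (32.9%) on the y axis, in arbitrary units. Each point is a library, and the dashed lines join libraries 1 and 2 of a group; library 3 of each group lies near that line.

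**Figure D2:**
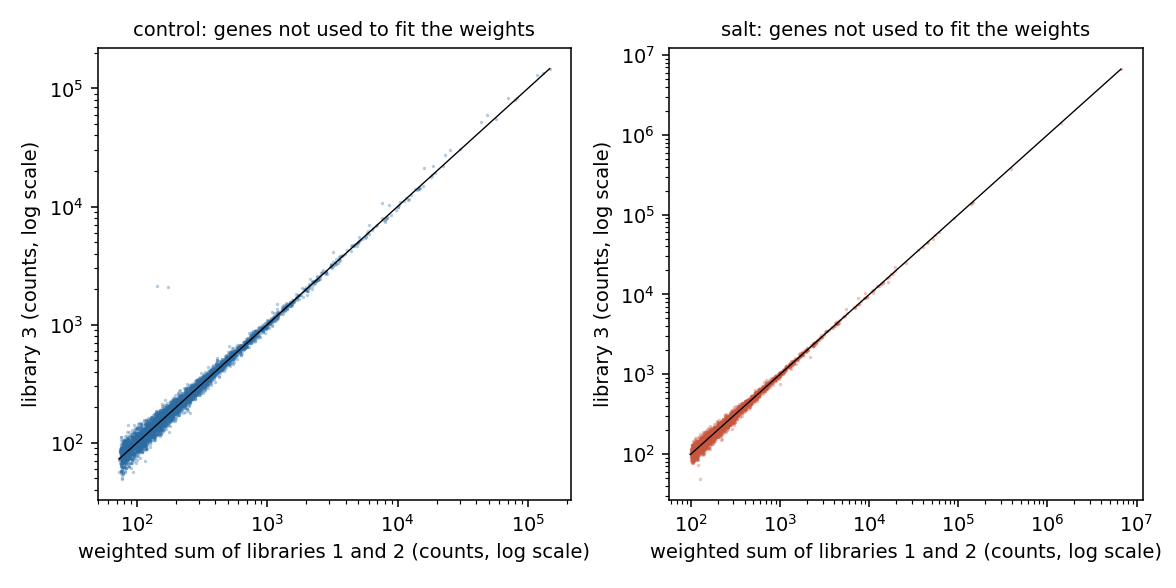
Counts of library 3 (y axis, log scale) against the weighted sum of libraries 1 and 2 (x axis, log scale) for genes left out of the fit, in control (left) and salt (right). Each point is a gene and the line marks equality; 2 control genes and 1 salt gene depart by more than 2-fold.

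Over all 6 libraries, 746 of 23666 genes were called, 290 higher and 456 lower in salt (edgeR quasi-likelihood test, adjusted p under 0.05). The genes that rose did so by a median of 1.09 on the log2 scale (10th to 90th percentile 0.74 to 2.01), and those that fell by a median of -1.15 (-2.52 to -0.73). Of the calls, 456 exceeded 2-fold, 170 higher and 286 lower, and 109 exceeded 4-fold, 30 higher and 79 lower. The called genes came from 716 assembly components. In all 746 the salt and control libraries did not overlap. Leaving out libraries could therefore hardly reverse a direction, so a kept direction is no separate test. Without both libraries 3 the same test called 0 of 25248 genes, with 1736 (6.88%) at an unadjusted p under 0.05, against 4709 (19.9%) with all 6 libraries, and DESeq2 called 83. Recovery of changed genes was simulated for 6 libraries only, and fewer libraries give less power. The 0 calls therefore do not show that no gene changed. Leaving out control library 3 alone left 33 calls and salt library 3 alone 20, whereas leaving out salt library 1 or 2 left 408 and 410. Calls beyond 2-fold numbered 698 without control library 1, 33 without control library 3 and 20 without salt library 3.

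The balance of higher and lower calls depended on the scaling and on other choices. With TMM factors 38.9% of calls were higher in salt. Library-total scaling gave 100 higher and 948 lower (9.54% higher), and upper-quartile scaling gave 379 higher and 337 lower (52.9%). Limma-trend on TPM, which changes the values and the test together, gave 68 higher and 308 lower (18.1%). DESeq2 gave 295 higher and 799 lower (26.97%), and edgeR without a filter 604 higher and 1682 lower (26.4%). The median log2 fold change of tested genes was 0.0034 with TMM, -0.28 with library-total scaling and -0.13 with limma-trend on TPM.

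**Figure D3:**
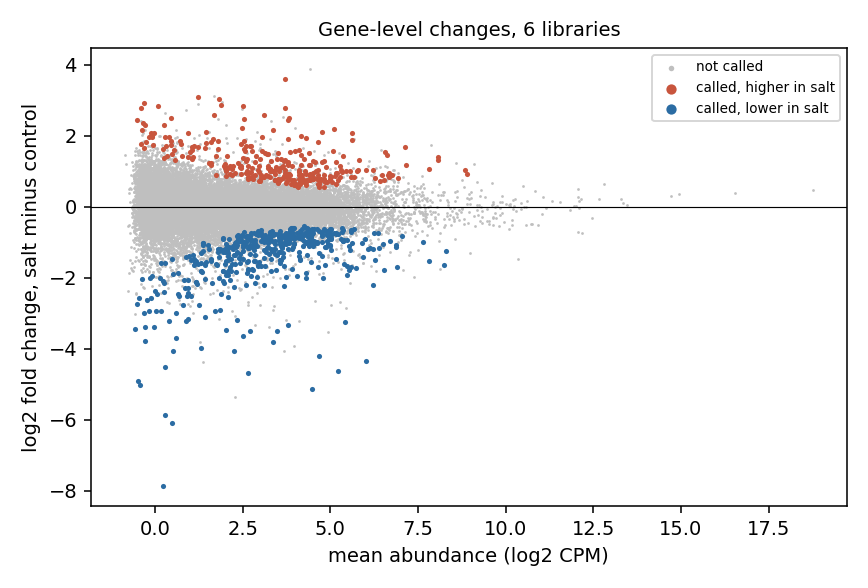
Log2 fold change, salt minus control (y axis), against mean abundance in log2 CPM (x axis) for 23666 genes over 6 libraries. Called genes are coloured, 290 higher and 456 lower in salt; without both libraries 3 none of these was called by the same test.

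Among called genes whose groups did not overlap and whose mean log2 CPM was at least 1, the largest rise was in TRINITY_DN1849_c0_g2, with 2 isoforms and a longest isoform of 708 nt. It went from 1.96 ± 0.81 CPM in control to 24.3 ± 2.89 CPM in salt (SD, n = 3 libraries each), a log2 fold change of 3.61 (SE 0.27, edgeR adjusted p = 0.0015). TRINITY_DN117471_c0_g1, a single isoform of 1450 nt, went from 0.472 ± 0.041 to 4.14 ± 0.41 CPM (log2 fold change 3.11, SE 0.25, edgeR adjusted p = 0.0019), on 7 to 10 counts per control library. The largest fall was in TRINITY_DN234_c0_g1, with a longest isoform of 1113 nt, from 42.4 ± 26.7 to 1.203 ± 0.380 CPM (log2 fold change -5.13, SE 0.68, edgeR adjusted p = 0.023). Its control libraries ranged from 15.2 to 68.6 CPM. TRINITY_DN100133_c0_g1, a single isoform of 675 nt, went from 11.6 ± 4.5 to 0.452 ± 0.251 CPM (log2 fold change -4.67, SE 0.44, edgeR adjusted p = 0.0043), on 4 to 9 counts per salt library. Without both libraries 3 these log2 fold changes were 3.52, 3.12, -5.41 and -4.48, with edgeR adjusted p of 0.527, 0.527, 0.706 and 0.589 in the test without a replicate block. With the block, although no label pairs the numbers, the edgeR adjusted p were 0.0188, 0.0188, 0.0560 and 0.0210. The call of TRINITY_DN234_c0_g1 was also lost on leaving out control library 3 (adjusted p = 0.117) or salt library 1, 2 or 3 (0.0914, 0.0839 and 0.137) and without a filter (0.155), and that of TRINITY_DN100133_c0_g1 on leaving out salt library 3 (0.0696). Over the alternatives the edgeR, DESeq2 or limma adjusted p of these genes, in the order named, reached at most 0.527, 0.527, 0.706 and 0.589. The lowest edgeR or DESeq2 adjusted p were 9.35e-56, 7.37e-15, 3.44e-24 and 1.07e-55. That of TRINITY_DN234_c0_g1 came from DESeq2 and the others from edgeR without a filter, over 164158 genes. These fits counted each library 3 as a separate plant, so such low values are not a measure of certainty.

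**Figure D4:**
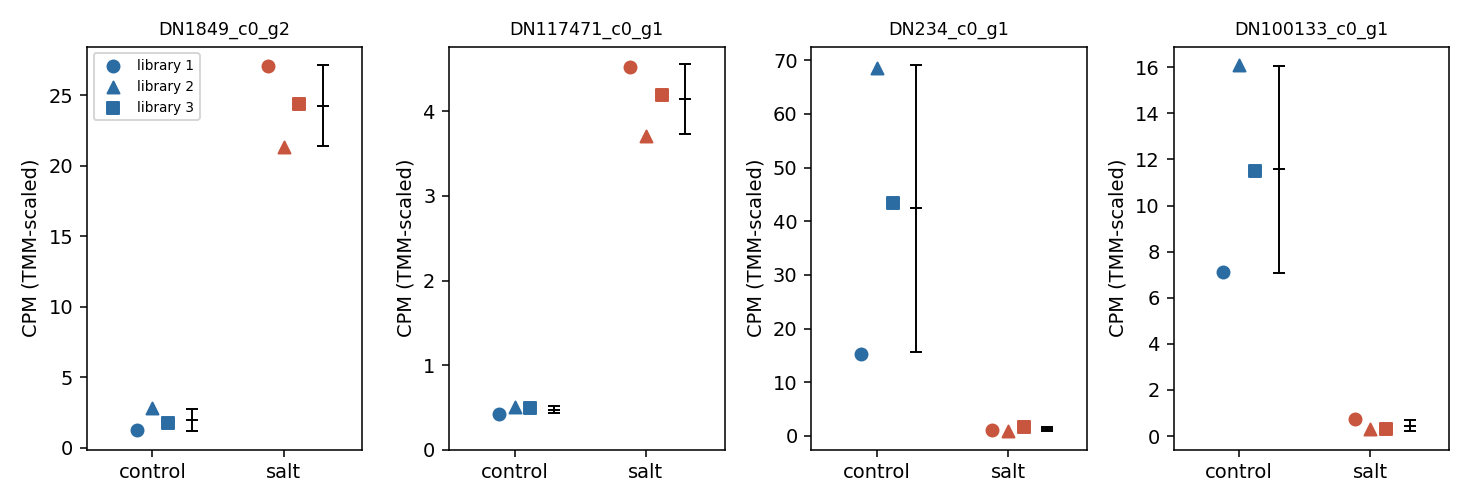
TMM-scaled CPM (y axis, from 0) of the 4 named genes in control and salt libraries (x axis); circles, triangles and squares are libraries 1, 2 and 3, and the bar beside them is the mean with its SD (n = 3). In each panel the salt and control points do not overlap, and library 3 lies between libraries 1 and 2 of its group except for salt library 3 of TRINITY_DN234_c0_g1 (1.63 CPM, against 1.07 and 0.908).

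The response was also followed in plants compared 1 to 1, using libraries 1 and 2 only. Across the 23666 tested genes, the log2 ratio of salt 1 to control 1 correlated with that of salt 2 to control 2 (Pearson r = 0.35, Spearman rho = 0.34, across genes, which are not independent replicates), and 62.2% of genes had the same sign. For the crosswise comparison, salt 1 to control 2 against salt 2 to control 1, r was -0.18 and 49.7% of genes had the same sign. Both salt libraries lay on one side of both control libraries in 39.1% of genes, where an exchangeable set of 4 libraries gives 33.3%. Both libraries numbered 1 lay on one side of both numbered 2 in 40.1% of genes, and the crosswise split (control 1 and salt 2 against control 2 and salt 1) parted the libraries in 20.8%. With the third libraries included, salt and control did not overlap in 6231 genes (26.3%). Chance gives 10% for 6 separate libraries, and 33.3% if each library 3 lies between libraries 1 and 2 in every gene. Among genes with at least 200 counts in libraries 1 and 2, library 3 did so in 82.9% (control) and 66.2% (salt). Neither value is therefore the chance share for these libraries.

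Called genes were more frequent among abundant genes, with 447 of 7889 in the highest tertile of mean abundance (5.67%), 216 of 7888 in the middle tertile (2.74%) and 83 of 7889 in the lowest (1.05%). The power of the test, which also rises with counts, was not separated from a difference in response. The share of calls that were higher in salt was 42.5%, 31.0% and 39.8% in these tertiles, a difference past the threshold (Fisher's exact test, two-sided, across genes, which are not independent replicates, p = 0.0162, adjusted over 3 tests p = 0.0487). It was lost without control library 2 (adjusted p = 0.351) or salt library 1 (0.167). Between the highest and the lowest tertile the share of higher calls differed by 2.75 percentage points, and by -11.0 without salt library 2 (adjusted p = 0.0145). By length, 181 of 436 called genes over 1500 nt were higher (41.5%), 105 of 293 between 500 and 1500 nt (35.8%) and 4 of 17 under 500 nt (23.5%), and these shares did not differ past the threshold (adjusted p = 0.132). Genes with 4 or more isoforms had 133 higher calls of 307 (43.3%), those with 2 to 3 had 80 of 223 (35.9%) and those with 1 had 77 of 216 (35.6%), also not past it (adjusted p = 0.132). Leaving out control library 1 gave adjusted p of 0.00036 for length and 0.0025 for isoform number in the same Fisher's tests across genes. The stricter filter gave 0.041 and 0.037, and the replicate block 0.00065 for length. In the other alternatives that gave a value, neither length nor isoform number passed. Under the block the abundance difference turned to -3.35 (Fisher's exact test, adjusted p = 0.0089). Without both libraries 3 the same edgeR test called 0 genes, which left no calls to compare by class.

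No isoform of 48437 passed the threshold in the isoform-level test, with a smallest edgeR adjusted p of 0.121 and 4546 isoforms at an unadjusted p under 0.05, while limma-voom called 0 and DESeq2 called 2191. The test of relative isoform use called 17 of 9823 genes with at least 2 tested isoforms, and 206 had an unadjusted p under 0.05. Another split of the 6 libraries gave 21 usage calls, and the replicate block gave 0. On simulated data with 200 genes switched 4-fold or 16-fold, the usage test made 19 and 23 false calls. Because genes had been switched there, these are no null count for the 17. Of the 17 genes, 1 was also called for its total level. Leaving out single libraries gave 3 to 11 usage calls (7 and 11 without control library 1 or 2, 5 without control library 3, 9 and 11 without salt library 1 or 2, and 3 without salt library 3), and leaving out both libraries 3 gave 7, of which 0 were among the 17. Of all genes, 1 had at least 10 counts in every control library and 0 in every salt library, and 0 genes had the opposite pattern; another split of the 6 libraries also gave 1. Leaving out control library 1 gave 5 such genes, and leaving out salt library 2 or 3 gave 3 and 4, all present in control only. Leaving out salt library 1 gave 8, of which 5 were present in salt only and 3 in control only.

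Counts were concentrated in few transcripts in both groups, more so in the salt libraries. Which RNA these transcripts are is not known, since no identifier carries a name. The shares in these total-RNA libraries are therefore not read as a change in leaf messenger RNA. The most abundant gene, a single isoform of 1693 nt, held 39.6% ± 1.6 of counts in control and 46.1% ± 3.2 in salt (SD, n = 3; exact permutation test, two-sided, p = 0.1, the smallest the design allows). The second, with a longest isoform of 2017 nt, held 8.58% ± 2.15 and 9.77% ± 0.05 (SD, n = 3). The 10 most abundant genes of each library held 58.8% ± 2.5 of counts in control and 66.5% ± 3.0 in salt (SD, n = 3; exact permutation p = 0.1, adjusted over 4 tests 0.2), and the 100 most abundant 71.9% ± 3.7 and 77.4% ± 2.0 (SD, n = 3; exact permutation p = 0.2, adjusted 0.267). Relative to the other genes, after TMM scaling, 0 of the 20 genes with the highest mean abundance were called. Genes with at least 1 count numbered 114268 ± 7368 in control and 107348 ± 381 in salt (SD, n = 3; exact permutation p = 0.1, adjusted 0.2). After each library was thinned to the smallest total these numbers were 106678 ± 10219 and 102726 ± 3912 (SD, n = 3; exact permutation p = 0.6). Library totals did not differ past the spread between libraries (exact permutation p = 0.5). Without both libraries 3 the 10 most abundant genes held 59.1% ± 3.5 and 66.3% ± 4.2 of counts and the 100 most abundant 72.0% ± 5.3 and 77.3% ± 2.8 (SD, n = 2; exact permutation p = 0.333, the smallest that 2 against 2 allow, and 0.667). Genes detected then numbered 115962 ± 9557 and 107319 ± 535 (SD, n = 2; exact permutation p = 0.333), and for totals the exact permutation p was 0.667.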

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

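The tests without both libraries 3 (with edgeR, with DESeq2 and with the replicate block), library-total scaling without the 20 most abundant genes, and legacy = FALSE were chosen after the data were seen. Gene-level calls (746) were within 1.5 times that number under RLE, upper-quartile and library-total scaling, the stricter filter, DESeq2 and a non-robust fit. The same held without the 20 most abundant genes, in both fits. These settings called 491 to 739 of the 746. Direction, where tested, was kept, as non-overlap favours. The count was 2286 without a filter, 474 with limma-voom and 376 with limma-trend on TPM; without both libraries 3 it was 0 with edgeR and 83 with DESeq2. Calls beyond 2-fold (456) became 1232 without a filter and 0 without both libraries 3. Leaving out 1 library gave 20 to 1103 gene-level calls and 20 to 698 beyond 2-fold, the lowest without a library 3. Isoform-level calls (0) became 331 without a filter and 2191 with DESeq2, and stayed at 0 with each library left out. Isoform usage calls (17) became 8 under a weaker filter, 2 under a stricter one, 7 without both libraries 3 and 3 to 11 with 1 library left out. Genes present in 1 group only (1) became 4 at a minimum of 5 counts, 0 at 20, 8 when 1 count was allowed in the other group, 6 without both libraries 3 and 1 to 8 with 1 library left out. Library-level differences kept their direction without both libraries 3. The difference in the share of higher calls between the last and first class, in percentage points, was 7.67 for isoform number, 17.98 for length and 2.75 for abundance. For isoform number it was 11.4 under the stricter filter, past the threshold, -4.57 without a filter and -66.7 to 21.7 with 1 library left out. For length it was 17.8 under the stricter filter, past the threshold, -2.01 without a filter and 2.38 to 20 with 1 library left out, and for abundance 10.45 under the stricter filter (adjusted p = 0.0227) and -11.0 to 20.04 with 1 library left out. Fewer calls, down to 20 genes, lie behind the widest of these; for the rest the cause was not tested. A class without calls gave no value for abundance without a filter or without either library 3, and for length without either library 3. With the replicate block (the number as a term) there were 2974 gene-level calls, 1140 beyond 2-fold, 0 usage calls, and class differences of 13.7 for length and, turned in direction, -3.35 for abundance, both past the threshold. The replicate block without both libraries 3 gave 239 gene-level calls, all beyond 2-fold, 1 usage call and a class difference past the threshold only for abundance, 30 (adjusted p = 0.0187). It called 3 of the 4 named genes (edgeR adjusted p = 0.0188, 0.0188 and 0.0210) but not TRINITY_DN234_c0_g1 (0.0560). Deviations of same-numbered libraries from the group means correlated at 0.43, 0.48 and 0.03, and 5 of 6 libraries correlated best with their own number. With legacy = FALSE there were 747 gene-level calls, 728 of them among the 746, 0 isoform-level calls and 20 usage calls, 7 of them among the 17. Of 60 recomputed fold changes of the 4 named genes, 49 kept the call, 11 lost it and 0 reversed, as non-overlap favours. At this depth 4.48% of simulated 4-fold isoform changes were recovered. The gene lists were not run, as no identifier is paired with a name.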

Other observations

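The tests of the third libraries and of the number axis were chosen after those patterns were seen, as was the simulation of unchanged groups; the test of scaling and the counts over other splits were fixed before their results were seen.

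The third library of each group sat where a mixture of libraries 1 and 2 would sit. A separate plant with its own variation is argued against by a median-based deviation from the mixture of at most 2.89% beyond counting error. A separate plant simulated from the control libraries, with a spread between plants set at 35%, gave 53.8%. Libraries 1 and 2 deviated by 13.8% to 37.6%, but their fits rested on library 3 alone. A library 3 between them forces such deviations, so these do not measure a plant's own variation. Plain copying of reads is argued against because squared residuals, in the median, were at least 2.0 times their Poisson value. Simulated copies gave 0.659 and a simulated pool sequenced anew gave 1.28. Neither simulation held errors in assigning shared reads to genes, which could raise the value for copies too, so copying with such errors is not excluded. Of 50 genes with at least 50 counts in library 1 or 2 and at most 1 in the other (17 in control, 33 in salt), all 50 were found in library 3, at median ratios of 0.37 and 0.41 in control and 0.43 and 0.48 in salt, near the mixing weights. A candidate explanation is therefore pooled RNA, or a mixed library, of plants 1 and 2, sequenced anew. It stays a hypothesis, since no label describes it. It leaves open why squared residuals, in the median at least 2.0 times their Poisson value, also exceeded the 1.28 of the simulated pool. It also leaves open the 2 genes that were over 2-fold from the mixture in control library 3 and the 1 in salt library 3.

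If the third libraries are mixtures, the count of gene-level calls may be inflated without any salt effect. With no gene changed, simulated data with evenly mixed libraries 3 gave up to 465 calls and 19.4% of genes at an unadjusted p under 0.05, close to the 19.9% observed, while the observed 746 calls lay above that range. The simulation took genes as independent and drew the spread of each separate plant independently. In the data libraries 1 and 2 differed alike in both groups (r = 0.57 for the log2 ratio of library 2 to 1), so the simulated range may not match the data. Without both libraries 3 the unblocked edgeR test called 0 genes (1736 at an unadjusted p under 0.05) and DESeq2 83. With the replicate number as a block edgeR called 239, of which 153 were among the 746, though no label pairs the numbers. How many of the 746 reflect salt therefore remains open.

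Among the 10 splits of the 6 libraries, too few for a share under 0.05, 1 gave as many gene-level calls as the real 746, the real split itself, and the highest other gave 0. For calls beyond 2-fold 1 split, the real one, gave 456, and the highest other gave 0. For isoform usage 3 of 10 splits gave at least the real 17, the highest other giving 21. At isoform level the real split and the highest other gave 0, as did all 10 splits. The real split alone keeps each library 3 with libraries 1 and 2 of its group, so the other splits are no null value for it: with no gene changed, simulated mixed libraries 3 gave 203 to 465 gene-level calls under the real grouping.

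Libraries 1 and 2 differed from each other in much the same way in control and salt plants. Across 11621 genes with a mean of at least 50 counts, the log2 ratio of library 2 to library 1 correlated between the groups at r = 0.57 (rho = 0.46, across genes). Among the 4 libraries numbered 1 and 2, edgeR called 109 genes between the numbers and 0 between salt and control, each in a fit without the other as a term. Deviations of the libraries numbered 3 from their group means correlated at 0.03 only. A near-even mixture of libraries 1 and 2 would deviate little from its group mean, so that value does not count against a shared difference. A trend with length is argued against by rho of 0.033 between that ratio and the length of the longest assembled isoform in control and -0.031 in salt. RNA integrity was not tested, since no integrity value was used. Raw sequencing depth is argued against because library 2 was deeper than library 1 by 3.37 M counts in salt and shallower in control; this holds for raw totals only, since TMM-scaled totals, which also carry composition, were larger for library 2 in both groups. A shared batch, growing position or parent of equal numbers may lie behind it, with 10 genes private to the same number in both groups and 1 private crosswise; these cannot be told apart, since no label records them.

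Under library-total scaling 9.54% of calls were higher in salt, and 49.0% were once the 20 most abundant genes were left out, against 38.9% with TMM. The share had been predicted to come within 10 percentage points of the TMM value if these genes set the balance, and it fell just outside on the high side. With the same 20 genes left out, TMM gave 39.2%, from which 49.0% lies less than 10 points away, so the outcome depends on which TMM fit is taken. The 20 genes held 63.1% ± 2.8 of counts in control and 70.3% ± 2.6 in salt (SD, n = 3).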
